A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

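Poly(A) RNA of 12 yeast cultures was measured by RNA sequencing, in 4 groups of 3 libraries labelled as biological replicates: untreated and MMS-treated wild type, and untreated and MMS-treated hel2 deletion strain. RNA had been extracted with hot phenol, and libraries made with oligo-dT selection, per the labels' protocols. The values used were the read counts per gene that the authors deposited as 1 table for all libraries. STAR 2.5.1a, Subread with featureCounts 1.4.6-p5 and Salmon are named without further detail, per the submitters' processing notes. The genome build, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads shared between paralogs, and reads of overlapping or antisense genes, can therefore stand in the count of a neighbour or relative, and values of genes with close relatives carry that uncertainty. All 12 columns of the table were matched to a sample.

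The table held whole numbers in 7230 lines for 7109 gene identifiers. Of these, 97 identifiers stood on several lines with equal counts and were used once. Symbols were taken from the RefSeq annotation of assembly R64 for 6042 identifiers, and that annotation was used only for names and for which genes neighbour each other. Library totals ran from 36472686 to 53638964 counts. The lowest chi-square per degree of freedom between replicates was 65, so the spread between cultures exceeded counting noise at this depth.

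Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 with robust estimates in R 4.3.3. All 12 libraries shared 1 estimate of spread, without a block, since the labels do not say what a replicate number shares. In the data, treated and untreated wild type libraries of the same number deviated together, with correlations of 0.39, 0.18 and 0.19. The other 15 pairs of the same number ran from -0.62 to 0.08, none over 0.1. Of the 12 libraries, 4 deviated most like the libraries of their own number in other groups. These values do not establish a pairing. The filter filterByExpr left 6463 genes. The 5 comparisons were MMS in each strain, the deletion against the wild type without and with MMS, and the difference of the MMS effects. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and counts at 2-fold took genes that passed with a fitted change of at least 2-fold. Log2 fold changes are given with an approximate standard error (SE), the size of the change divided by the square root of its F statistic. Levels are CPM, counts divided by the TMM-scaled library size, as mean and SD of 3 libraries.

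Gene groups were 26 lists, with 872 members found in the table and 5 not found (ARS1, Q0020, Q0158, 15S_RRNA and 21S_RRNA). Separate lists of 16 glucose-repressed genes and of 10 damage genes were used only in the closing parts. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01 and adjusted over the lists within a comparison. The same test with an estimated correlation is given beside each list that passed. Members of each list were also adjusted over the list alone. Comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined, with exceptions named in the closing parts.

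Genes were named by a fixed rule. It took HEL2, GCN4, GCN2 and other genes of ribosome quality control and the integrated stress response, the markers HIS3, LEU2, MET17 and URA3, and the 2 genes next to HEL2. Per comparison it took the 6 largest rises and 6 largest falls among genes that passed, with a standard symbol and a mean log2 CPM of at least 4. In comparisons of 2 groups these genes also had no overlap of libraries. Per comparison and list it took up to 3 members that passed with the largest change. Other genes named were chosen after their values were seen.

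Alternatives were median-ratio scaling (RLE), library-size scaling, DESeq2 1.42.0, limma-voom, no filter, a mean log2 CPM of at least 4, a replicate block, only the libraries compared, leaving out each library in turn, the estimated correlation, and the 2 Gcn4 lists joined. An alternative without genes at least 5 times above both other replicates in 1 library was added after the data were seen. Further ones were added later still, a list without HEL2 and a replicate block in the wild type libraries alone. Where a library was left out, the 2 that stayed shared the spread of the other groups. Intervals came from 10000 resamples of genes, which treats genes as independent and can make the intervals too narrow.

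The procedure was tested on simulated data, drawn from the means and library sizes of the real samples with known changes. At each fold 66 or 67 genes were changed, in 1 group, about as many up as down. The real comparisons had up to 75.4% of genes passing and shifts of whole gene groups, which the simulation lacked. It also drew genes independently, with a spread set by the trend over expression rather than by each gene. Genes high in 1 library were absent from it. The shares below can thus be more favourable than in the real data. In edgeR, a 1.5-fold change was found for 56.7% of the changed genes for MMS in the wild type (6456 genes run) and 58.2% for MMS in the deletion strain (6454 genes run). It was found for 55.2% for the untreated strains and 64.2% for the strains with MMS. At 2-fold these shares were 95.5, 94, 94 and 95.5%. For the difference of the MMS effects they were 28.4% at 1.5-fold and 74.6% at 2-fold with changes placed in the treated deletion strain, and 22.4 and 80.6% with changes placed in the untreated wild type. At 4-fold all changed genes were found in each comparison. The false share of edgeR calls was 3.45% for MMS in the wild type and 5.62% for MMS in the deletion strain. It was 4.6% for the untreated strains and 6.49% for the strains with MMS. For the difference of the MMS effects it was 7.53 and 4.26%, with changes placed as above. In DESeq2 it ran from 8.33 to 18.8%. Protein levels, translation and growth were not analysed here, and raw reads were not realigned.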

Results

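Messenger RNA was measured by poly(A) RNA sequencing in budding yeast of the BY4741 background, an auxotrophic laboratory strain. There were 4 groups of 3 libraries labelled as biological replicates. They were the wild type and a hel2 deletion strain, each without treatment and after methyl methanesulfonate (MMS), an alkylating agent that damages DNA and RNA. HEL2 encodes a ubiquitin ligase that recognises collided ribosomes in ribosome-associated quality control. Cells had been grown in rich medium to an optical density of about 0.5, and MMS was given for 90 min at 30 °C. The labels give no dose of MMS. Libraries are named here by group and replicate, from WT_1 to hel2_MMS_3.

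The deposited table held whole read counts per gene for 12 libraries. The untreated wild type libraries held 49717561, 41395764 and 45019819 counts, and the MMS-treated wild type libraries 36472686, 40641054 and 47742712. The untreated deletion libraries held 48425721, 45890253 and 53638964 counts, and the MMS-treated deletion libraries 44673122, 48787901 and 50966308. In each library 6719 to 6791 genes had a count, and 6463 genes were tested. TDH3, a glycolytic enzyme gene, was the most abundant gene in every library, with 3.87 to 6.81% of the counts. Cytosolic ribosomal protein genes took 24.5, 26.7 and 24.8% of the counts in the untreated wild type and 7.06, 8.88 and 7.75% with MMS. In the deletion strain they took 23.6, 21.3 and 22.5% without MMS and 4.33, 4.12 and 4% with MMS. The first principal component held 76.5% of the variance and parted treated from untreated libraries, and the second held 11.2%. WT_MMS_1 stood apart from the other two libraries of its group, at 43.2 on the second component against 21.8 and 21.4. The SD of its log2 deviation from them over genes was 0.415, the highest of the 12 libraries.

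HEL2 (YDR266C) had 2105, 1869 and 2431 counts in the untreated wild type and 928, 1522 and 2185 in the MMS-treated wild type. It had 27, 19 and 20 counts in the untreated deletion strain and 35, 39 and 29 with MMS. The log2 fold change of HEL2 in the deletion strain was -6.82 ± 0.20 (SE, n = 3 per group) without MMS, with an adjusted p of 6.53e-10. With MMS it was -5.98 ± 0.19, with an adjusted p of 3.32e-10. Of the genes next to HEL2 on the chromosome, PEX10 differed by 0.11 (adjusted p = 0.463) and CIA1 by -0.11 (adjusted p = 0.408) without MMS. With MMS PEX10 was higher in the deletion strain by 0.45 (adjusted p = 0.000414). CIA1 was lower by 0.20 (adjusted p = 0.0332), at 0.14 under library-size scaling, with its call lost without WT_MMS_3 (adjusted p = 0.144), hel2_MMS_1 (adjusted p = 0.107), hel2_MMS_2 (adjusted p = 0.0727) or hel2_MMS_3 (adjusted p = 0.0526). The call of CIA1 was also lost with the replicate block (adjusted p = 0.0506), with only the libraries compared (adjusted p = 0.0684) and with a mean log2 CPM of at least 4 (adjusted p = 0.119).

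The strains also differed at LEU2 (YCL018W), a leucine synthesis gene and an auxotrophic marker of this background. LEU2 had 16, 19 and 2 counts in the untreated wild type and 28, 20 and 21 with MMS. It had 21322, 24146 and 28105 counts in the untreated deletion strain and 19719, 20882 and 19374 with MMS. The log2 difference was 10.73 ± 0.40 without MMS (adjusted p = 3.73e-08) and 9.19 ± 0.37 with MMS (adjusted p = 6.46e-09). The markers MET17, with 16 to 105 counts, and URA3, with 2 to 12 counts outside WT_MMS_2, stayed low in both strains. HIS3 (YOR202W), a histidine synthesis gene, had 3334 to 7513 counts in the wild type libraries and 4082 to 18212 in the deletion libraries.

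**Figure D1:**
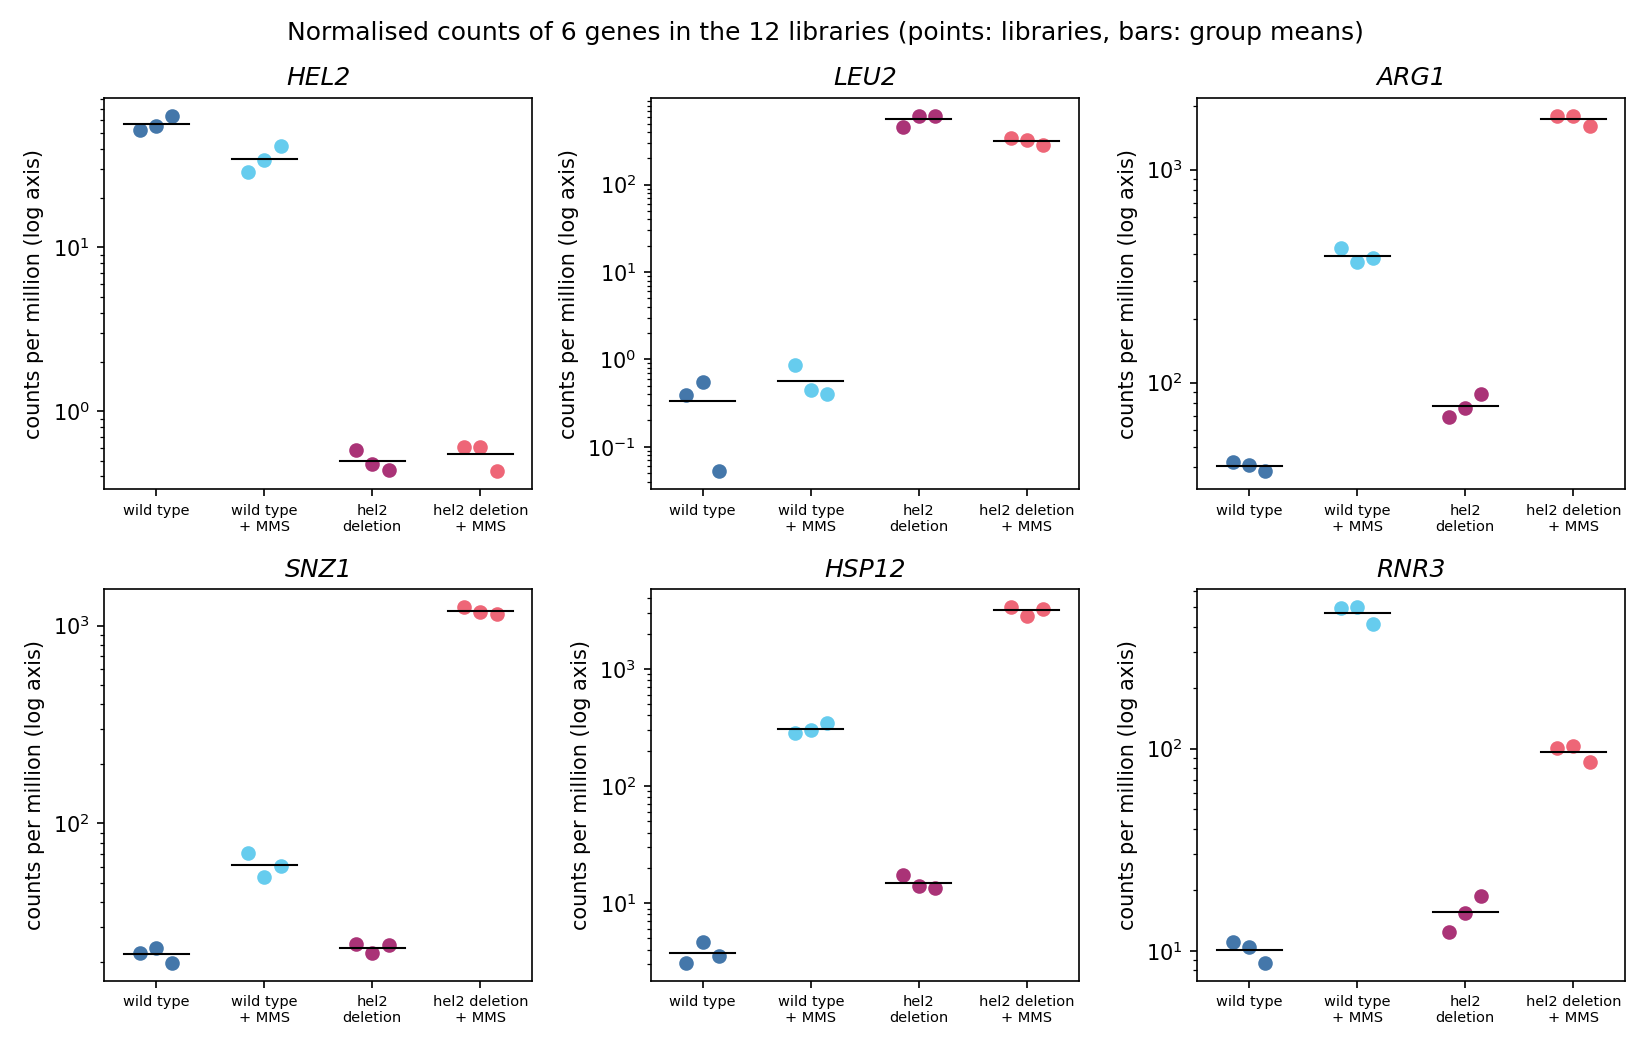
Normalised CPM (log axis) of 6 genes in each of the 12 libraries, with points for libraries and bars for the means of 3 replicates. HEL2 fell from a mean of 56.6 in the untreated wild type to 0.499 in the untreated deletion strain, and SNZ1 reached a mean of 1180 in the MMS-treated deletion strain against 61.7 in the MMS-treated wild type.

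To see how the wild type responded to the alkylating agent, MMS-treated and untreated wild type cells were compared. DDR2 (YOL052C-A), a stress gene induced by DNA damage, rose from 3.45 ± 0.158 to 959 ± 413 CPM (scaled counts, mean ± SD, n = 3), a log2 fold change of 8.12 ± 0.31 (SE, adjusted p = 2.19e-10). HSP12 (YFL014W), a membrane-protecting stress protein gene, rose by 6.37 ± 0.18 (adjusted p = 1.5e-11) and TFS1 (YLR178C), a carboxypeptidase Y inhibitor gene, by 5.66 ± 0.19 (adjusted p = 5.49e-11). RNR3 (YIL066C), the damage-inducible large subunit of ribonucleotide reductase, rose by 5.54 ± 0.17 (adjusted p = 3.23e-11). The histone gene HTA2 (YBL003C) fell by 3.91 ± 0.13 (adjusted p = 6.43e-11), and the ribosomal protein gene RPL9A (YGL147C) fell from 1750 ± 119 to 189 ± 40.2 CPM. Of 6463 genes tested, 4515 passed, 2302 higher and 2213 lower, and 1861 of them changed at least 2-fold.

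Of 44 general stress genes, known targets of Msn2 and Msn4, 42 rose and 2 did not pass, with a median log2 fold change of 3.31 (adjusted p = 4.42e-46, or adjusted p = 0.0339 with an estimated correlation). In WT_MMS_1 this list lay 0.40 above the mean of the other two libraries. Of 37 DNA damage genes, 24 rose and 3 fell, with a median of 0.98 (adjusted p = 1.26e-08, or adjusted p = 0.0226 with an estimated correlation) and WT_MMS_1 at -0.15. Only 1 member fell when WT_2, WT_3 or WT_MMS_1 was left out. DDI2 and DDI3, both cyanamide hydratase genes, rose by 5.42 ± 0.21 and 4.85 ± 0.19. Of 34 oxidative stress genes, 29 rose and 1 fell, with a median of 1.17 (adjusted p = 5.78e-11, but adjusted p = 0.0745 with an estimated correlation) and WT_MMS_1 at 0.22. GTT2, a glutathione transferase gene, rose by 5.05 ± 0.11, and FLR1, a drug efflux transporter gene, by 4.94 ± 0.16. Of 24 autophagy genes, 20 rose, with a median of 1.53 (adjusted p = 2.97e-06, or adjusted p = 0.0378 with an estimated correlation) and WT_MMS_1 at -0.18. Of 38 proteasome genes, 36 rose, with a median of 0.82 (adjusted p = 6.92e-07, but adjusted p = 0.293 with an estimated correlation) and WT_MMS_1 at -0.27. Adjusted over the list alone, the counts of these 5 lists were unchanged.

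All 138 cytosolic ribosomal protein genes fell, with a median of -2.25 (adjusted p = 4.42e-46, but adjusted p = 0.0745 with an estimated correlation) and WT_MMS_1 at -0.23. Of 108 ribosome biogenesis genes, 107 fell, with a median of -1.85 (adjusted p = 3.24e-34, but adjusted p = 0.0745 with an estimated correlation) and WT_MMS_1 at -0.44. NSR1, which acts in processing of ribosomal RNA, fell by 2.73 ± 0.08. All 19 tRNA synthetase genes fell, with a median of -1.26 (adjusted p = 2.8e-08, but adjusted p = 0.0745 with an estimated correlation) and WT_MMS_1 at -0.11. Of 10 histone genes, 9 fell, with a median of -2.49 (adjusted p = 1.53e-09, but adjusted p = 0.0745 with an estimated correlation) and WT_MMS_1 at -0.29. Of 22 G2/M genes, 19 fell, with a median of -1.16 (adjusted p = 3.6e-06, but adjusted p = 0.135 with an estimated correlation) and WT_MMS_1 at -0.24. CLB2, a mitotic cyclin gene, fell by 2.36 ± 0.17. Of 21 M/G1 genes, 17 fell and 2 rose, or 17 and 3 adjusted over the list alone, with a median of -1.13 (adjusted p = 4.77e-06, or adjusted p = 0.0226 with an estimated correlation). Of 24 ergosterol synthesis genes, 20 fell and 1 rose, with a median of -0.97 (adjusted p = 1.32e-05, but adjusted p = 0.237 with an estimated correlation) and WT_MMS_1 at 0.27. Apart from M/G1, the counts adjusted over the list alone were the same.

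Gcn4 targets are the transcriptional output of the integrated stress response in yeast. Of 48 Gcn4 targets in amino acid synthesis, 26 rose, 17 fell and 5 did not pass, or 27 and 17 adjusted over the list alone, with a median of 0.34 (adjusted p = 0.0306, but adjusted p = 0.669 with an estimated correlation). WT_MMS_1 stood at 0.17, and the call was lost without WT_3 (adjusted p = 0.0533), WT_MMS_1 (adjusted p = 0.172) or hel2_1 (adjusted p = 0.057). It was also lost with limma-voom (adjusted p = 0.0899), with a mean log2 CPM of at least 4 (adjusted p = 0.12) and with a replicate block in the wild type libraries alone (adjusted p = 0.0793). The arginine synthesis genes ARG1 and ARG3 rose by 3.27 ± 0.11 and 3.30 ± 0.09. Of 26 other Gcn4 targets, 14 rose and 10 fell, with a median of 0.51 (adjusted p = 0.2). Library-size scaling gave medians of 0.66 and 0.81 for these Gcn4 lists. The GCN4 transcript itself fell by 0.66 ± 0.09 (adjusted p = 1.35e-05). Of 40 genes of ribosome quality control and the integrated stress response, 22 fell and 6 rose, with a median of -0.30, or 0.02 under library-size scaling (adjusted p = 0.0166, but adjusted p = 0.327 with an estimated correlation), and WT_MMS_1 at -0.20. Without HEL2, the list had a median of -0.28 (adjusted p = 0.0189, but adjusted p = 0.319 with an estimated correlation). ASC1, which encodes a ribosome-bound scaffold protein, fell by 1.5 ± 0.16, and MBF1, a coactivator of Gcn4, rose by 1.38 ± 0.09.

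Shifts were also seen for 4 other lists. Of 29 Hsf1-driven chaperone genes, 15 rose and 7 fell, with a median of 0.45 (adjusted p = 0.000549, but adjusted p = 0.179 with an estimated correlation) and WT_MMS_1 at -0.16. Of 23 genes of the unfolded protein response, 16 rose and 1 fell, or 17 and 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.0306, but adjusted p = 0.0921 with an estimated correlation). Of 24 iron regulon genes, 16 rose and 6 fell, with a median of 0.78 (adjusted p = 0.0138, but adjusted p = 0.539 with an estimated correlation) and WT_MMS_1 at 0.33. Of 36 respiratory chain genes, 20 fell and 6 rose, with a median of -0.35 (adjusted p = 0.0273, but adjusted p = 0.509 with an estimated correlation) and WT_MMS_1 at 0.28. That call was lost without WT_MMS_2 (adjusted p = 0.0605), under library-size scaling with a median of -0.04 (adjusted p = 0.103) and with a mean log2 CPM of at least 4 (adjusted p = 0.0663). At that filter the call for the unfolded protein response was lost as well (adjusted p = 0.0663). The glycolysis list did not pass, with a median of -0.25 and a mean of 0.09 (adjusted p = 0.898), and its median was 0.04 under library-size scaling. In it 5 genes rose and 8 fell, and WT_MMS_1 stood at 0.39. Without WT_MMS_1 the median was -0.39, with 4 higher and 10 lower. With library-size scaling the chaperone median was 0.77 and that of the unfolded protein response 0.83. Apart from the unfolded protein response, the counts adjusted over the list alone were the same.

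Of the 6463 genes tested, 4614 had no overlap between treated and untreated libraries, where chance gives 10%. Among the 111 genes named for this comparison that passed, URA3, UBP6, MCM5 and RQC2 had an overlap, and the rule for names itself asks for none in part of them. Under library-size scaling the median of all genes moved to 0.33 in this comparison, to 0.61 for MMS in the deletion strain, to 0.11 and 0.37 for the deletion without and with MMS, and to 0.23 for the difference of the MMS effects. Of the passing genes, 51% were higher here, and 69.3% under library-size scaling.

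To learn whether cells without Hel2 respond to MMS in the same way, treated and untreated deletion cells were compared. HSP12 (YFL014W) rose from 15 ± 2.05 to 3150 ± 268 CPM, a log2 fold change of 7.72 ± 0.19 (SE, adjusted p = 2.51e-12). SNZ1 (YMR096W), a vitamin B6 synthesis gene that Gcn4 activates, rose from 23.6 ± 1.3 to 1180 ± 49 CPM, by 5.65 ± 0.12 (adjusted p = 1.54e-12). ALD3 (YMR169C), an aldehyde dehydrogenase gene, rose by 5.86 ± 0.26 (adjusted p = 6.77e-10). URA1 (YKL216W), a pyrimidine synthesis gene, fell by 4.36 ± 0.11 (adjusted p = 3.49e-12), and RPL9A (YGL147C) fell by 4.35 ± 0.16 (adjusted p = 4.37e-11). In all 4874 genes passed, 2535 higher and 2339 lower, and 2395 of them changed at least 2-fold.

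Of the 48 Gcn4 targets in amino acid synthesis, 35 rose and 12 fell, with a median of 0.93 (adjusted p = 8.29e-07, but adjusted p = 0.321 with an estimated correlation). ARG1 rose by 4.48 ± 0.11, ARG3 by 5.10 ± 0.09 and ARG4, also of arginine synthesis, by 3.84 ± 0.09. Of the 26 other Gcn4 targets, 15 rose and 7 fell, with a median of 1.01 (adjusted p = 1.25e-05, but adjusted p = 0.0695 with an estimated correlation). TMT1, a methyltransferase gene, rose by 4.87 ± 0.10. Library-size scaling moved the medians of the Gcn4 lists to 1.49 and 1.57. The GCN4 transcript fell by 0.90 ± 0.09 (adjusted p = 5.47e-07). Of the ribosome quality control and stress response genes, 11 rose and 20 fell, and the list did not pass, with a median of -0.15, or 0.40 under library-size scaling (adjusted p = 0.0524). It passed without WT_2 (adjusted p = 0.0498), hel2_2 (adjusted p = 0.044) or hel2_3 (adjusted p = 0.0466), with no filter (adjusted p = 0.045), without genes high in 1 library (adjusted p = 0.0441) and without HEL2 in the list (median -0.23, adjusted p = 0.0475, but adjusted p = 0.406 with an estimated correlation). With a mean log2 CPM of at least 4 the median was -0.41 (adjusted p = 0.0577). RQT4, of the complex that splits collided ribosomes, rose by 1.06 ± 0.15, and ASC1 fell by 2.79 ± 0.16. The counts of these 3 lists were the same adjusted over the list alone.

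Of the general stress genes, 43 rose and none fell, with a median of 3.55 (adjusted p = 2.73e-34, but adjusted p = 0.0695 with an estimated correlation). Of the proteasome genes, 37 rose, with a median of 1.21 (adjusted p = 4.95e-08, but adjusted p = 0.242 with an estimated correlation). Chaperone genes rose in 18 cases and fell in 9, with a median of 1.25 (adjusted p = 0.000193, but adjusted p = 0.156 with an estimated correlation), led by HSP42 at 5.41 ± 0.20. Oxidative stress genes rose in 26 cases and fell in 2, with a median of 1.20 (adjusted p = 3.92e-07, but adjusted p = 0.145 with an estimated correlation). Autophagy genes rose in 21 cases and fell in 1, with a median of 1.55 (adjusted p = 3.29e-06, but adjusted p = 0.0695 with an estimated correlation). DNA damage genes rose in 24 cases and fell in 7, with a median of 0.79, or 1.35 under library-size scaling (adjusted p = 0.00132, but adjusted p = 0.101 with an estimated correlation). GAS3, a cell wall enzyme gene in that list, fell by 3.15 ± 0.13. The counts of these 6 lists were the same adjusted over the list alone.

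Of the cytosolic ribosomal protein genes, 137 fell and 1 rose, with a median of -3.02 (adjusted p = 1.98e-48, but adjusted p = 0.0894 with an estimated correlation). Ribosome biogenesis genes fell in 106 of 108 cases, with a median of -2.13 (adjusted p = 4.95e-32, but adjusted p = 0.109 with an estimated correlation). All 19 tRNA synthetase genes fell, with a median of -1.54 (adjusted p = 3.76e-07, but adjusted p = 0.118 with an estimated correlation). Glycolysis genes fell in 14 of 17 cases and rose in 2, with a median of -1.07 (adjusted p = 0.00678, but adjusted p = 0.607 with an estimated correlation). HXK2, the main hexokinase gene, fell by 3.56 ± 0.11. G1/S genes fell in 19 cases and rose in 2, with a median of -0.68 (adjusted p = 0.000869, but adjusted p = 0.328 with an estimated correlation), among them the cyclin gene CLN2 at -2.74 ± 0.08. All 10 histone genes fell, with a median of -1.72 (adjusted p = 4.36e-07, but adjusted p = 0.145 with an estimated correlation). G2/M genes fell in 19 cases, or 20 adjusted over the list alone, with a median of -1.36 (adjusted p = 1.13e-05, but adjusted p = 0.191 with an estimated correlation). Ergosterol genes fell in 23 cases, with a median of -1 (adjusted p = 8.12e-06, but adjusted p = 0.227 with an estimated correlation). M/G1 genes fell in 14 cases and rose in 4, with a median of -1.09 (adjusted p = 0.00947, but adjusted p = 0.101 with an estimated correlation), and their call was lost with a mean log2 CPM of at least 4 (adjusted p = 0.0577). Medians under library-size scaling were -0.98 for tRNA synthetases, -0.51 for glycolysis, -0.13 for G1/S, -0.80 for G2/M, -0.44 for ergosterol and -0.53 for M/G1. Apart from G2/M, the counts adjusted over the list alone were the same.

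Not passing was the unfolded protein response list, with 7 genes higher and 10 lower, a median of -0.12, a mean of 0.09 and 0.44 under library-size scaling (adjusted p = 0.971). Its median was -0.19 without hel2_1. The respiratory chain list did not pass either, with a median of 0.04, a mean of -0.04 and a median of -0.01 under median-ratio scaling and 0.60 under library-size scaling (adjusted p = 0.888). Its median was 0.07 without hel2_1, 0.02 without hel2_2, 0.00 without hel2_3, 0.01 without hel2_MMS_1 and 0.14 with a mean log2 CPM of at least 4. Of the 6463 genes tested, 5264 had no overlap between treated and untreated libraries, where chance gives 10%, and all 115 named genes that passed were among them. Of the passing genes, 52% were higher, and 74.4% under library-size scaling.

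Across the 6463 genes, the MMS effect in the deletion strain and that in the wild type had a Pearson r of 0.82, with a jackknife SE of 0.0377, and a Spearman rho of 0.83. Genes are not independent replicates. The total least squares slope of the deletion strain on the wild type was 1.22, with a jackknife SE of 0.0708. Genes higher in both numbered 1874 against 903 if the calls were independent, and genes lower in both 1785 against 801. Of the genes higher in the wild type, 99 were lower in the deletion strain, and 67 went from lower to higher.

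**Figure D2:**
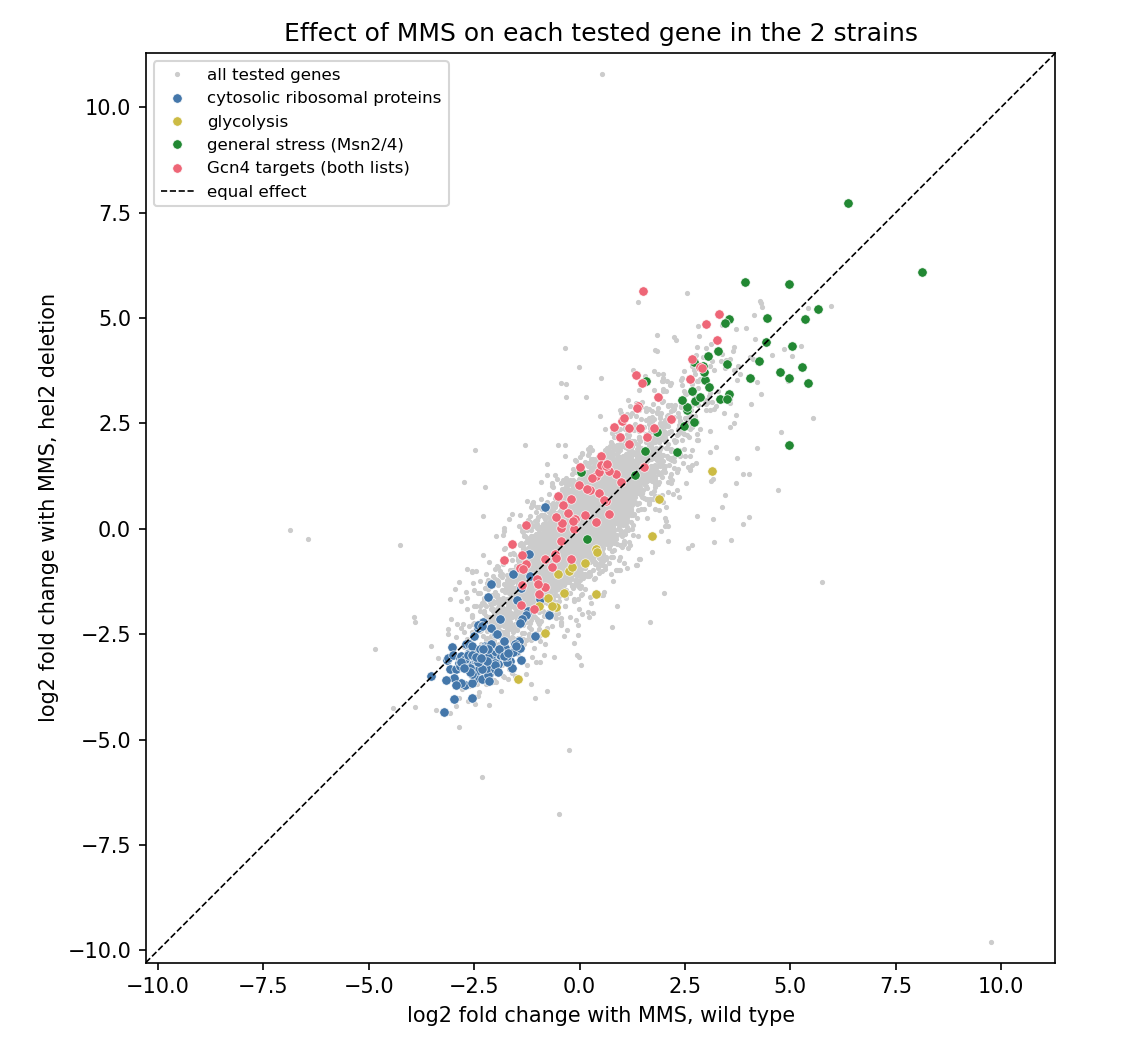
Log2 fold change with MMS in the hel2 deletion strain (vertical axis) against that in the wild type (horizontal axis) for 6463 tested genes, with 4 groups of genes in colour and a dashed line where both are equal. The 48 Gcn4 targets of amino acid synthesis had medians of 0.34 in the wild type and 0.93 in the deletion strain, and the 17 glycolysis genes had medians of -0.25, or 0.04 under library-size scaling, and -1.07.

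To find what differed in unstressed cells, the untreated strains, which differ at both HEL2 and LEU2, were compared. The general stress genes DDR2, TMA10 and HSP12 were higher in the deletion strain, DDR2 by 3.19 ± 0.25 (SE, adjusted p = 9.14e-06), TMA10 (YLR327C) by 2.44 ± 0.19 (adjusted p = 8.63e-06) and HSP12 by 2.00 ± 0.15 (adjusted p = 7.15e-06). HSP12 went from 3.75 ± 0.785 to 15 ± 2.05 CPM. TSL1 (YML100W), of trehalose synthesis, was higher by 1.92 ± 0.14 (adjusted p = 4.73e-06), and HXK1 (YFR053C), a hexokinase gene, by 1.83 ± 0.11 (adjusted p = 1.07e-06). SIR2 (YDL042C), a histone deacetylase gene of silenced chromatin, was lower by 0.97 ± 0.10 (adjusted p = 8.7e-05). AAH1 (YNL141W), an adenine deaminase gene, was lower by 0.77 ± 0.09 (adjusted p = 0.000219). In all, 554 genes passed, 339 higher and 215 lower, and 46 of them differed at least 2-fold.

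Of the general stress genes, 26 were higher and 18 did not pass, or 31 and 13 adjusted over the list alone, with a median of 0.69 (adjusted p = 2.32e-44, but adjusted p = 0.081 with an estimated correlation). Among chaperone genes 11 were higher, or 13 adjusted over the list alone, with a median of 0.25 (adjusted p = 1.71e-09, but adjusted p = 0.0971 with an estimated correlation). HSP78, a mitochondrial disaggregase gene, was higher by 1.26 ± 0.10 and HSP104, its cytosolic relative, by 1.03 ± 0.10. Without WT_1 or WT_2, 7 chaperone genes passed. Among autophagy genes 7 were higher, or 8 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.000939, but adjusted p = 0.182 with an estimated correlation), and 3 without WT_1 and 4 without WT_3 or hel2_1. Among iron regulon genes 8 were higher, or 12 adjusted over the list alone, with a median of 0.27 (adjusted p = 1.01e-05, but adjusted p = 0.385 with an estimated correlation), and 5 without WT_2, WT_3 or hel2_3. ARN2, a siderophore transporter gene, was higher by 0.78 ± 0.13.

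Ribosome biogenesis genes were lower in 26 cases, or 34 adjusted over the list alone, with a median of -0.27 (adjusted p = 4.47e-16, but adjusted p = 0.347 with an estimated correlation). That count was 17 without WT_1, 16 without WT_2 or hel2_2, 14 without WT_3, 13 without hel2_1 and 52 without WT_MMS_1. Ribosomal protein genes were lower in 19 cases, or 32 adjusted over the list alone, with a median of -0.24 (adjusted p = 1.05e-11, but adjusted p = 0.407 with an estimated correlation). That count was 4 without WT_1, 3 without WT_2 or hel2_2, 10 without WT_3 or hel2_MMS_2, 5 without hel2_1, 12 without hel2_MMS_1, 11 without hel2_MMS_3 and 52 without WT_MMS_1. NSR1 was lower by 0.60 ± 0.08 and RPS28B by 0.54 ± 0.09. Among tRNA synthetase genes 2 were lower, or 5 adjusted over the list alone, with a median of -0.17 (adjusted p = 0.000939, but adjusted p = 0.359 with an estimated correlation), and 7 without WT_MMS_1. The medians of these 3 lists were -0.17, -0.14 and -0.07 under library-size scaling.

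Of the Gcn4 targets in amino acid synthesis, 9 were higher and 1 lower, or 12 and 2 adjusted over the list alone, with a median of 0.00 and a mean of 0.10 (adjusted p = 0.211), and a median of 0.09 under library-size scaling and -0.02 under median-ratio scaling. The list passed under library-size scaling (adjusted p = 0.0234) and without hel2_1 (adjusted p = 0.0134), and the higher and lower genes numbered 4 and 0 without WT_3, 4 and 1 without hel2_3 and 14 and 4 without WT_MMS_1. The median was -0.04 without WT_3, 0.03 without hel2_1 and -0.05 without hel2_3. ARG1 was higher by 0.93 ± 0.10. Among other Gcn4 targets 6 were higher and 2 lower, or 8 and 7 adjusted over the list alone, with a median of 0.04, or 0.14 under library-size scaling and 0.02 under median-ratio scaling (adjusted p = 0.527). Those counts were 3 and 2 without WT_1, hel2_MMS_2 or hel2_MMS_3, 2 and 1 without WT_2, WT_3 or hel2_2, 3 and 1 without hel2_3 and 8 and 7 without WT_MMS_1, and the median was 0.07 without WT_1 and 0.02 without WT_3. PCL5, a cyclin gene that acts in Gcn4 turnover, was higher by 0.78 ± 0.08 (adjusted p = 4.71e-05). GCN4 differed by 0.04 (adjusted p = 0.851) and GCN2, the kinase gene of this response, by 0.01 (adjusted p = 0.978).

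Of the ribosome quality control and stress response genes, 4 were lower and 1 higher, or 10 and 1 adjusted over the list alone, HEL2 among them, with a median of -0.06, or 0.04 under library-size scaling and -0.09 under median-ratio scaling, and a mean of -0.23 (adjusted p = 0.000182, but adjusted p = 0.275 with an estimated correlation). Without HEL2, the gene deleted by design, the list did not pass, with a median and a mean of -0.06 (adjusted p = 0.0809), nor did it with a mean log2 CPM of at least 4 (adjusted p = 0.0595). The median was -0.10 without hel2_1. The lower genes numbered 1 without WT_1, WT_2, WT_3 or hel2_2, 2 without hel2_1 or any of the 3 MMS-treated deletion libraries and 12 without WT_MMS_1. The higher gene was MBF1, by 0.43 ± 0.09. For mitochondrially encoded genes, only 2 of which had enough counts to be tested, the median was -0.80 (adjusted p = 0.0477, but adjusted p = 0.311 with an estimated correlation), with none past the gene test and 2 lower adjusted over the list alone. That list call was lost without WT_1 (adjusted p = 0.0632), WT_2 (adjusted p = 0.0969), WT_MMS_1 (adjusted p = 0.058), WT_MMS_3 (adjusted p = 0.0543) or hel2_2 (adjusted p = 0.101). It was also lost under median-ratio scaling or with limma-voom (adjusted p = 0.0509 in each), with no filter (adjusted p = 0.0875) and without genes high in 1 library (adjusted p = 0.0619).

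Of the 6463 genes tested, 2063 had no overlap between the untreated strains, where chance gives 10%, and all 58 named genes that passed were among them. The count of 554 genes was 312 without WT_1, 305 without WT_2, 319 without WT_3, 1163 without WT_MMS_1, 336 without hel2_1 and 329 without hel2_2. DESeq2 called 841 genes, of which 50.2% were higher, against 61.2% in edgeR and 85.4% in edgeR with library-size scaling.

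To ask how the strains differed after treatment, the MMS-treated strains were compared. SNZ1 (YMR096W) was higher in the deletion strain by 4.26 ± 0.11 (SE, adjusted p = 1.12e-10), with 1180 ± 49 against 61.7 ± 8.51 CPM, and its partner SNO1 (YMR095C) by 2.53 ± 0.16 (adjusted p = 5.71e-08). HSP12 was higher by 3.35 ± 0.15 (adjusted p = 5.22e-09). HXT5 (YHR096C), a hexose transporter gene of slow-growing cells, was higher by 2.91 ± 0.20 (adjusted p = 1.06e-07). SCW10 (YMR305C), TOS6 (YNL300W) and CIS3 (YJL158C), each coding for a cell wall protein, were at -3.23 ± 0.12 (adjusted p = 1.08e-09), -3.30 ± 0.16 (adjusted p = 5.89e-09) and -3.15 ± 0.14 (adjusted p = 4.46e-09). PIR3, a wall protein gene, and DSE1, of daughter cell separation, went the other way, at 2.07 ± 0.19 and 1.97 ± 0.09, and no list of cell wall genes was tested. In all, 3999 genes passed, 2070 higher and 1929 lower, and 954 of them differed at least 2-fold.

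Of the Gcn4 targets in amino acid synthesis, 35 were higher, 7 lower and 6 did not pass, also adjusted over the list alone, with a median of 0.70, or 1.05 under library-size scaling (adjusted p = 1.63e-11, but adjusted p = 0.237 with an estimated correlation), and WT_MMS_1 at 0.17. The lower genes numbered 4 without WT_MMS_1 or hel2_MMS_3. ARG3 was higher by 2.52 ± 0.08, ARG56 (YER069W) by 2.17 ± 0.09 and ARG1 by 2.14 ± 0.10, the last with 1730 ± 106 against 393 ± 31.2 CPM. Of the other Gcn4 targets, 18 were higher and 3 lower, or 18 and 4 adjusted over the list alone, with a median of 0.96 (adjusted p = 1.63e-11, or adjusted p = 0.0162 with an estimated correlation) and WT_MMS_1 at 0.14. Without WT_MMS_3, 5 of them were lower. GCN4 itself differed by -0.20 ± 0.09 and did not pass (adjusted p = 0.0566). GCN2 was higher by 0.37 ± 0.10 (adjusted p = 0.00636). Of the ribosome quality control and stress response genes, 14 were higher and 17 lower, also adjusted over the list alone, with a median of 0.01, a mean of -0.19 and a median of -0.05 under median-ratio scaling and 0.34 under library-size scaling (adjusted p = 0.155), and WT_MMS_1 at -0.20. That median was -0.04 without WT_MMS_1 or with a mean log2 CPM of at least 4, 0.03 without WT_MMS_2, 0.06 without WT_MMS_3, 0.02 without hel2_MMS_1 and -0.01 without hel2_MMS_2. RQT4 was higher by 1.37 ± 0.15 and ASC1 lower by 1.66 ± 0.16.

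General stress genes were higher in 39 cases and lower in 2, with a median of 0.82 (adjusted p = 1.52e-10, but adjusted p = 0.237 with an estimated correlation) and WT_MMS_1 at 0.40. Chaperone genes were higher in 20 cases and lower in 5, with a median of 0.49 (adjusted p = 4.47e-05, but adjusted p = 0.19 with an estimated correlation) and WT_MMS_1 at -0.16. HSP42 was higher by 2.30 ± 0.18. Proteasome genes were higher in 26 cases and lower in 2, with a median of 0.44 (adjusted p = 0.00156, but adjusted p = 0.568 with an estimated correlation) and WT_MMS_1 at -0.27. Autophagy genes were higher in 15 cases and lower in 3, with a median of 0.69 (adjusted p = 0.00419, but adjusted p = 0.19 with an estimated correlation) and WT_MMS_1 at -0.18. Respiratory chain genes were higher in 20 cases and lower in 4, with a median of 0.26 (adjusted p = 0.0105, but adjusted p = 0.557 with an estimated correlation) and WT_MMS_1 at 0.28. The lower ones numbered 2 without WT_1, WT_2, WT_3, WT_MMS_1, hel2_2, hel2_3, hel2_MMS_2 or hel2_MMS_3. M/G1 genes were higher in 11 cases and lower in 4, with a median of 0.20 (adjusted p = 0.00662, but adjusted p = 0.19 with an estimated correlation). That median was 0.33 without WT_MMS_1, and the lower genes numbered 1 without hel2_MMS_1 and 2 without hel2_MMS_3. It was 0.13 under median-ratio and 0.55 under library-size scaling, and the latter gave 0.80 for chaperones, 0.77 for the proteasome and 0.59 for the respiratory chain. Adjusted over the list alone, the counts of these 6 lists were the same.

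Glycolysis genes were lower in all 17 cases, with a median of -0.97 (adjusted p = 9.02e-07, but adjusted p = 0.402 with an estimated correlation) and WT_MMS_1 at 0.39. HXK2 had 208 ± 8.06 against 939 ± 104 CPM, a difference of -2.17 ± 0.10, and the alcohol dehydrogenase gene ADH1 differed by -1.94 ± 0.15. Ribosomal protein genes were lower in 116 cases and higher in 5, or 118 and 5 adjusted over the list alone, with a median of -1.01 (adjusted p = 9.1e-20, but adjusted p = 0.237 with an estimated correlation) and WT_MMS_1 at -0.23. The higher ones numbered 3 without hel2_MMS_1. Ribosome biogenesis genes were lower in 64 cases and higher in 4, with a median of -0.61 (adjusted p = 1.63e-11, but adjusted p = 0.402 with an estimated correlation) and WT_MMS_1 at -0.44. G1/S genes were lower in 19 cases, or 19 with 1 higher adjusted over the list alone, with a median of -0.60 (adjusted p = 7.15e-08, but adjusted p = 0.237 with an estimated correlation) and WT_MMS_1 at -0.29. The cyclin gene PCL1 was lower by 2.46 ± 0.14. The medians of these 4 lists were -0.61, -0.67, -0.30 and -0.27 under library-size scaling. The counts of the glycolysis and ribosome biogenesis lists were the same adjusted over the list alone.

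Unfolded protein response genes were lower in 14 cases and higher in 2, with a median of -0.48, or -0.14 under library-size scaling (adjusted p = 0.00156, but adjusted p = 0.0784 with an estimated correlation), and WT_MMS_1 at -0.04. DNA damage genes were lower in 16 cases and higher in 10, with a median of -0.18, or 0.18 under library-size scaling (adjusted p = 0.0259, but adjusted p = 0.237 with an estimated correlation), and WT_MMS_1 at -0.15. That median was -0.05 without WT_MMS_2, and the call was lost with limma-voom (adjusted p = 0.118). RNR3 was lower by 2.29 ± 0.14 (adjusted p = 5.2e-08) and RNR1, the main large subunit of ribonucleotide reductase, by 2.23 ± 0.13 (adjusted p = 2.16e-08). Genes for tRNA synthetases were lower in 14 cases and higher in 1, with a median of -0.42 (adjusted p = 0.014, but adjusted p = 0.488 with an estimated correlation) and WT_MMS_1 at -0.11. That call was lost under library-size scaling, with a median of -0.10 (adjusted p = 0.076), and with a mean log2 CPM of at least 4 (adjusted p = 0.0644). Ergosterol genes were lower in 16 cases and higher in 3, with a median of -0.39, or -0.04 under library-size scaling (adjusted p = 0.015, but adjusted p = 0.568 with an estimated correlation), and WT_MMS_1 at 0.27. Adjusted over the list alone, the counts of these 4 lists were the same.

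Of the 6463 genes tested, 4415 had no overlap between the treated strains, where chance gives 10%. Among the 116 named genes that passed, GEX1 and URA3 had an overlap. Genes higher in the deletion strain both without and with MMS numbered 243 against 109 if the calls were independent, and those lower in both 177 against 64.2. Of the passing genes, 51.8% were higher, and 76.2% under library-size scaling.

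To test whether the MMS effect itself differed between the strains, the difference of the 2 MMS effects was fitted, deletion strain minus wild type. The MMS effect on SNZ1 was larger in the deletion strain by 4.15 ± 0.15 (SE, adjusted p = 7.15e-09), and that on ARG3 by 1.81 ± 0.12 (adjusted p = 6.53e-07). TKL2 (YBR117C), of the pentose phosphate pathway, differed by 2.77 ± 0.39 (adjusted p = 0.00035). RNR3 differed by -2.90 ± 0.20 (adjusted p = 9.83e-07), with a rise of 5.54 in the wild type and 2.64 in the deletion strain. HXK1 differed by -2.99 ± 0.15 (adjusted p = 9.48e-08), and SCW10 by -3.08 ± 0.16 (adjusted p = 9.48e-08). In all, 2587 genes passed, 1200 higher and 1387 lower, and 634 of them differed at least 2-fold.

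Of the Gcn4 targets in amino acid synthesis, 33 had a higher and 3 a lower MMS effect in the deletion strain, also adjusted over the list alone, with a median difference of 0.71 (adjusted p = 7.69e-13, but adjusted p = 0.318 with an estimated correlation) and WT_MMS_1 at 0.17. For the other Gcn4 targets these counts were 20 and 2, also adjusted over the list alone, with a median of 0.89 (adjusted p = 3.36e-14, or adjusted p = 0.00652 with an estimated correlation) and WT_MMS_1 at 0.14. The MMS effect on GCN4 itself differed by -0.24 ± 0.12 (adjusted p = 0.137). Respiratory chain genes differed upward in 17 cases and downward in 1, or 18 and 1 adjusted over the list alone, with a median of 0.32, or 0.58 under library-size scaling (adjusted p = 0.000847, but adjusted p = 0.458 with an estimated correlation), and WT_MMS_1 at 0.28. Proteasome genes differed upward in 16 cases and downward in 1, or 17 and 1 adjusted over the list alone, with a median of 0.30, or 0.54 under library-size scaling (adjusted p = 0.00228, but adjusted p = 0.717 with an estimated correlation), and WT_MMS_1 at -0.27. Chaperone genes differed upward in 15 cases and downward in 5, also adjusted over the list alone, with a median of 0.40 (adjusted p = 0.0418, but adjusted p = 0.533 with an estimated correlation) and WT_MMS_1 at -0.16. That call was lost without WT_2 (adjusted p = 0.0548), WT_3 (adjusted p = 0.0526), WT_MMS_2 (adjusted p = 0.0593) or hel2_1 (adjusted p = 0.068), and under library-size scaling (median 0.62, adjusted p = 0.0651).

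M/G1 genes differed upward in 7 cases and downward in 1, also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0224, but adjusted p = 0.178 with an estimated correlation). That call was lost without WT_MMS_3 (adjusted p = 0.0552), where the median was 0.03, and with limma-voom (adjusted p = 0.0765). The median was 0.03 without WT_1 or hel2_1, 0.04 without WT_MMS_2, which left 8 and 3 genes, 0.11 without WT_2, 0.12 without hel2_MMS_3 and 0.16 without WT_MMS_1. It was 0.04 under median-ratio and 0.32 under library-size scaling, and 0.15 with a mean log2 CPM of at least 4. General stress genes did not pass, with 19 upward and 8 downward, also adjusted over the list alone, a median of 0.28, or 0.54 under library-size scaling (adjusted p = 0.316), and WT_MMS_1 at 0.40. They passed without WT_MMS_1, with a median of 0.41 (adjusted p = 0.0296), and had a median of 0.16 without WT_MMS_2, and 12 and 7 genes passed without hel2_MMS_1.

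All 17 glycolysis genes differed downward, with a median of -1.16 (adjusted p = 1.15e-08, but adjusted p = 0.458 with an estimated correlation) and WT_MMS_1 at 0.39. G1/S genes differed downward in 19 cases, with a median of -0.71 (adjusted p = 1.57e-11, but adjusted p = 0.178 with an estimated correlation) and WT_MMS_1 at -0.29, among them PCL1 by -2.57 ± 0.19. Ribosomal protein genes differed downward in 94 cases and upward in 3, or 95 and 4 adjusted over the list alone, with a median of -0.76 (adjusted p = 6.07e-14, but adjusted p = 0.458 with an estimated correlation) and WT_MMS_1 at -0.23. The upward ones numbered 5 without hel2_1. Ribosome biogenesis genes differed downward in 43 cases and upward in 5, or 44 and 5 adjusted over the list alone, with a median of -0.36 (adjusted p = 2.71e-05, but adjusted p = 0.717 with an estimated correlation) and WT_MMS_1 at -0.44. That median was -0.19 without WT_MMS_2, and the upward ones numbered 2 without WT_2, WT_3 or hel2_MMS_3, 3 without WT_1, hel2_2, hel2_3, hel2_MMS_1 or hel2_MMS_2 and 8 without hel2_1. Unfolded protein response genes differed downward in 13 cases, with a median of -0.42 (adjusted p = 0.00101, but adjusted p = 0.0638 with an estimated correlation) and WT_MMS_1 at -0.04. DNA damage genes differed downward in 15 cases and upward in 3, or 15 and 4 adjusted over the list alone, with a median of -0.29, or -0.07 under library-size scaling (adjusted p = 0.000895, but adjusted p = 0.178 with an estimated correlation), and WT_MMS_1 at -0.15. That scaling also gave -0.47 for G1/S, -0.15 for ribosome biogenesis and -0.19 for the unfolded protein response. HUG1, an inhibitor of ribonucleotide reductase, differed by -2.47 ± 0.14. For the lists given with 1 pair of counts in this paragraph, the counts adjusted over the list alone were the same.

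The call for HEL2 itself, 0.83 ± 0.27 (adjusted p = 0.0268), was lost without WT_3 (0.74), hel2_2 (0.80), hel2_3 (0.74), hel2_MMS_1 (0.76) or hel2_MMS_2 (0.75), and with limma-voom (0.80, adjusted p = 0.148). The deletion libraries held 19 to 39 counts of this deleted gene, so the difference sets its fall in the wild type against a floor. For the difference of the MMS effects, 46.4% of the passing genes were higher, and 66.6% under library-size scaling.

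**Figure D3:**
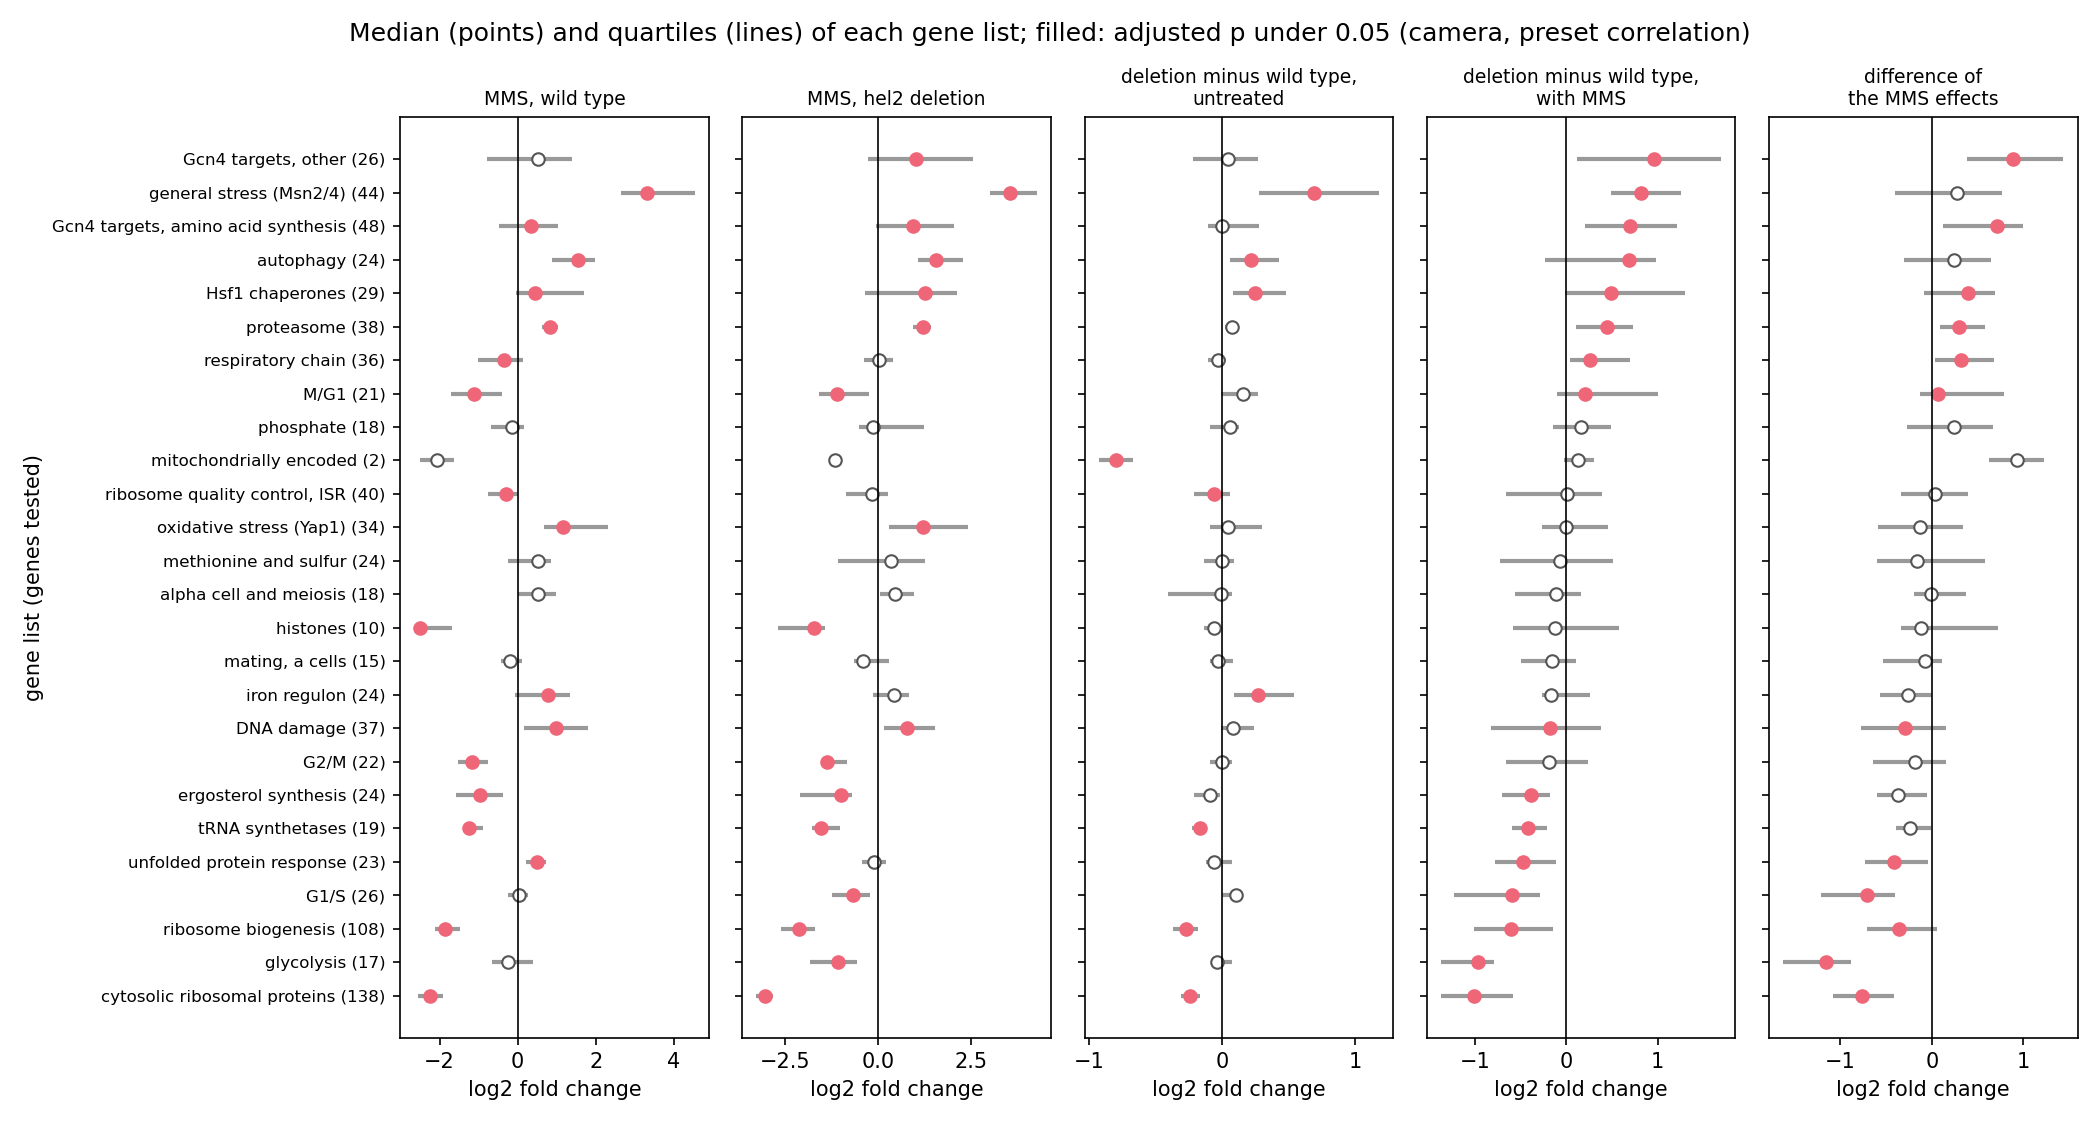
Median (points) and quartiles (lines) of the log2 fold change (horizontal axes) of 26 gene lists (vertical axis, with the number of genes tested) in the 5 comparisons, with filled points where the adjusted p was under 0.05. With MMS, the median of deletion strain minus wild type was 0.70 for Gcn4 targets in amino acid synthesis, -0.97 for glycolysis, -1.01 for ribosomal proteins and -0.18 for DNA damage, or 1.05, -0.61, -0.67 and 0.18 under library-size scaling.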

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

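Among the tests below, those of LEU2 and of scaling were chosen only after the result was seen. Each result here drew attention because the difference of the MMS effect between the strains passed its own test. For 2587 genes the MMS effect differed. Of 100 drawn splits of the libraries, 4 gave as many genes, the real one included, and the highest other gave 2902. Each split kept treated and untreated libraries apart and regrouped the strains within each. Splits that mixed the 2 strains among the treated libraries gave 2 genes at most. The other 7 drawn splits kept the treated strains apart and held all 4. The real split thus did not stand out among these 7, and 7 splits are too few for a share under 0.05. All 7 kept the difference between the treated strains, where 3999 genes passed, and large counts can come from that difference alone. These splits therefore cannot decide whether the count of 2587 exceeds chance. The highest other mixed only the untreated strains, with WT_1, hel2_1 and hel2_3 set beside the treated wild type.

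Of the 12 gene groups below, only other Gcn4 targets passed with an estimated correlation as well (adjusted p = 0.00652). Median differences were 0.71 for Gcn4 targets in amino acid synthesis and 0.89 for other Gcn4 targets. They were 0.30 for the proteasome, 0.40 for chaperones, 0.32 for the respiratory chain and 0.07 for M/G1 genes. Lower medians were found for glycolysis (-1.16), ribosomal proteins (-0.76), G1/S (-0.71), the unfolded protein response (-0.42), ribosome biogenesis (-0.36) and DNA damage (-0.29). Library-size scaling gave 0.97 for the Gcn4 amino acid list, 0.54 for the proteasome, 0.62 for chaperones, with that call lost, 0.58 for the respiratory chain and 0.32 for M/G1. It gave -0.47 for G1/S, -0.19 for the unfolded protein response, -0.15 for ribosome biogenesis and -0.07 for DNA damage. Among genes, SNZ1 differed by 4.15, HBT1, a gene of mating cell shape, by 2.5, HXT5 by 2.47 and TKL2 by 2.77. ARO5 differed by 3.86, with its call lost without hel2_2 (3.61, adjusted p = 0.0502) or hel2_3 (3.58, adjusted p = 0.0511). CLD1, a cardiolipin lipase gene, differed by 3.45, or 2.26 without WT_3. HXK1 differed by -2.99, and the membrane protein gene INA1 by -2.96. The cell wall genes CWP1, TIR1, SCW10 and TOS6 differed by -2.94, -3.02, -3.08 and -3.28.

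The pattern weighed is that Gcn4 targets in amino acid synthesis were higher in the deletion strain with MMS, by a median of 0.70 (adjusted p = 0.237 with an estimated correlation, which ends the call), but by 0.00 without it. There 9 members were higher and 1 lower, and the list passed under library-size scaling (adjusted p = 0.0234) and without hel2_1 (adjusted p = 0.0134). To weigh a stronger MMS response of the deletion strain in all genes, 10000 random lists were matched on the wild type response and on expression. Their central 95% of medians ran from -0.42 to 0.12, and the list had 0.93. That range treats genes as independent, while the estimated correlation within the list was 0.38 for MMS in the deletion strain. It can thus be too narrow, and no verdict is drawn from it. The 3 scalings tried did not remove the pattern. The lowest median difference of the MMS effects was 0.67, with an interval over resampled genes from 0.35 to 0.86. Effects of LEU2 and HEL2 cannot be told apart, since the strains differ in both, and the paired median of 0.71 for the list (0.39 to 0.89) only restates the pattern. An effect of losing HEL2 stays open and was not tested apart from LEU2.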

How the results depend on the processing

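The alternatives without genes high in 1 library, without HEL2 in its list and with a block in the wild type libraries alone were chosen only after the data were seen. What depth limits was not tested, since no depth was varied. With an estimated correlation between genes, 64 of 130 list results kept their side of the threshold and 66 lost their call, leaving 4, 0, 0, 1 and 1 lists in the 5 comparisons against 18, 17, 9, 16 and 12. The Gcn4 amino acid list stayed at 0.70 with MMS (adjusted p = 0.237) and at 0.71 for the difference of the MMS effects (adjusted p = 0.318), with no call under this setting, because the estimated correlation widens the spread of the test.

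With a mean log2 CPM of at least 4, fewer genes were tested, and counts at 2-fold fell to 1232 for MMS in the wild type, 26 for the untreated strains, 588 for the strains with MMS and 380 for the difference of the MMS effects. DESeq2 called 841 genes between the untreated strains, 422 higher and 419 lower, and the cause was not tested. The correlation of the MMS effects was 0.75 with no filter, 0.77 in DESeq2 and 0.87 without genes high in 1 library, against 0.82, and the cause was not tested. DESeq2 was run without filterByExpr, so its values differ from the main ones in filter as well as in tool.

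Under library-size scaling, which moves all genes, 12 results of named genes changed sign. They were GCN2 at 0.05, against -0.28, GCN20 at 0.08, SKI2 at 0.08 and SKI3 at 0.07 for MMS in the wild type, and GCN20 at 0.20, RKR1 at 0.12 and SKI2 at 0.32 for MMS in the deletion strain. For the strains with MMS they were CIA1 at 0.14, FAP1 at 0.03, GCN20 at 0.12, RKR1 at 0.17 and SUI3 at 0.05. Only GCN20 (adjusted p = 0.0497) and SKI2 (adjusted p = 0.0387) for MMS in the deletion strain passed in the new direction. The rest lost their call. URA3 with MMS in the wild type ran from -0.24 without WT_MMS_2 to 4.58 over the leave-outs, against 4.01.

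Leaving out 1 library gave 4219 to 4514 genes for MMS in the wild type, 4614 to 5105 for MMS in the deletion strain, 305 to 1163 for the untreated strains, 3581 to 4002 for the strains with MMS and 2193 to 2828 for the difference of the MMS effects. Counts at 2-fold ran from 1767 to 1948, 2364 to 2407, 40 to 48, 857 to 1103 and 553 to 735. The lists that passed ran from 17 to 18, 17 to 18, 8 to 11, 16 to 16 and 11 to 13. The Gcn4 amino acid median ran from 0.69 to 0.72 with MMS and 0.63 to 0.77 for the difference, the correlation from 0.80 to 0.84 and the slope from 1.16 to 1.26. Of the other results of named genes, 580 kept their side in DESeq2, 590 in limma-voom, 598 under RLE scaling, 605 with no filter and 594 without genes high in 1 library, while 16, 15, 5, 2 and 0 had no call, 9 of the 16 because DESeq2 gave them no adjusted p. Calls were lost for 35 under library-size scaling, besides those that changed sign, 17 with only the libraries compared and 4 with a mean log2 CPM of at least 4.

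With replicate number as a block, 4392, 4799, 402, 3836 and 2378 genes passed, all 130 list results kept their side, and 24 of the named gene results had no call. In the wild type alone, a block gave 4474 genes for MMS, and the calls of the Gcn4 amino acid list, GZF3 and MCM5 were absent while SKI7 and YIH1 passed, with no other call changed among lists and named genes.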

Other observations

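Among the tests in this part, that of the placement on chromosomes was chosen only after the result was seen. Phosphate and sulfur genes moved apart within their lists. PHO89 (YBR296C), a phosphate transporter gene, was higher in the deletion strain with MMS by 2.91 ± 0.18 (adjusted p = 4.35e-08), PHM8, a nucleotide phosphatase gene, by 1.55 ± 0.08 (adjusted p = 9.25e-09) and SPL2, a regulator of phosphate uptake, by 1.60 ± 0.19 (adjusted p = 1.04e-05). The phosphate list did not pass, with 8 higher and 4 lower of 18, also adjusted over the list alone, a median of 0.16, or 0.51 under library-size and 0.10 under median-ratio scaling (adjusted p = 0.168), and WT_MMS_1 at 0.30, and 7 and 2 without hel2_MMS_2, and its median was 0.08 without WT_MMS_2. In the sulfur list STR3 and STR2, of the path between cysteine and methionine, were higher by 2.41 ± 0.14 and 1.99 ± 0.12, while SAM1, which makes S-adenosylmethionine, was lower by 1.53 ± 0.12. That list had 8 higher and 11 lower of 24, also adjusted over the list alone, with a median of -0.07, or 0.28 under library-size and -0.13 under median-ratio scaling (adjusted p = 0.972), and WT_MMS_1 at 0.32. Its median was -0.02 without WT_MMS_1, with 10 higher and 8 lower, -0.14 without WT_MMS_2, -0.04 with no filter and 0.01 with a mean log2 CPM of at least 4.

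Of single cell wall genes, for which no list was tested, CWP1 (YKL096W), a mannoprotein gene, had 186, 1680, 316 and 371 CPM in the untreated and treated wild type and the untreated and treated deletion strain. TIR1 (YER011W), a mannoprotein gene of cold and low oxygen, had 154, 152, 190 and 23.2. Of 15 mating type a genes, 3 were higher and 7 lower with MMS, also adjusted over the list alone, with a median of -0.16, or 0.18 under library-size scaling (adjusted p = 0.504), and WT_MMS_1 at 0.16. That median was -0.09 with a mean log2 CPM of at least 4. Of 18 genes of alpha or sporulating cells, 2 were higher and 5 lower, also adjusted over the list alone, with a median of -0.11, or 0.24 under library-size and -0.17 under median-ratio scaling (adjusted p = 0.682), and WT_MMS_1 at 0.14. The lower ones numbered 3 and the higher 1 without WT_MMS_1 or hel2_MMS_2, and the median was -0.02 without WT_MMS_1, -0.18 without WT_MMS_2 and -0.05 with a mean log2 CPM of at least 4.

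For each comparison of 2 groups, the splits of 6 libraries into 3 and 3 are too few for a share under 0.05, since 1 of 10 is 0.1. The real split gave 4515 genes for MMS in the wild type, 4874 for MMS in the deletion strain, 554 for the untreated strains and 3999 for the strains with MMS, and the highest other gave 0, 0, 1 and 0.

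General stress genes were higher in the untreated deletion strain, by a median of 0.69, a call lost with an estimated correlation (adjusted p = 0.081). Glucose running out was argued against, for the genes covered, by 16 glucose-repressed genes, none of which passed between the untreated strains. They had a median difference of 0.02, with an interval from -0.17 to 0.19 that treats genes as independent. The hexokinase gene HXK1, higher in the untreated deletion strain, was not among the 16. MMS reaching the untreated cultures cannot be told apart from a response of the strain itself by the test run. That test used a separate list of 10 damage genes, all of which rose with MMS in both strains. Their median difference between the untreated strains was 0.0602 of their MMS effect in the deletion strain, and that of the stress genes 0.195. The interval of the difference, from -0.00582 to 0.224, held 0. No such ratio was computed for the 37 DNA damage genes, with medians of 0.08 between the untreated strains and 0.79 for MMS in the deletion strain. An effect of the LEU2 difference on the general stress genes was not tested.

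In 66 cases, 58 genes stood at least 5 times above both other replicates in 1 library. YER188W had 1061468 counts in WT_MMS_1, 2.91% of that library, and 1337240 in hel2_3, and YER187W had 886931 in hel2_MMS_1. Extra copies of a chromosome region were argued against by the 4 nearest genes, whose median log2 ratio over 59 cases was 0.01, with an interval from -0.04 to 0.07. Copies of a single gene would leave its neighbours unchanged, so that test does not bear on them. Placement by chance could have given the share of 19.6% on chromosome X, 10 of 51 genes, since random draws gave 11.8 to 23.5%. That test counted all 51 genes alike, whatever their level. YJR015W, RSM26, NUP192, GCD14, RCY1, GZF3 and LCB3, at 3250 to 17300 CPM in 1 library, lie on chromosome X. Of the other cases at 3250 CPM or more, YER188W and YER187W lie on chromosome V and MCM5 on XII. The placement of the highest cases was not tested apart. Apart from extra copies of a region, no biological explanation was tested.

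In such genes 1 library set the size of the change. For MMS in the wild type GZF3 was at -6.44 (adjusted p = 0.0161) and at -0.75 without WT_1, with adjusted p = 0.0541 without WT_MMS_1 and 0.051 without WT_MMS_2. For MMS in the deletion strain NUP192 was at -5.24 (adjusted p = 0.0139) and at -0.85 without hel2_1, and RSM26 at -6.77 (adjusted p = 0.0136) and at -0.80 without hel2_2. For the strains with MMS GCD14 was at -7.12 (adjusted p = 0.0204) and at -0.36 without WT_MMS_3, with adjusted p = 0.0645, 0.0653 and 0.0643 without hel2_MMS_1, hel2_MMS_2 and hel2_MMS_3. URA3 was at -4.28 (adjusted p = 0.0248) and at -0.02 without WT_MMS_2, with adjusted p = 0.0598, 0.0784 and 0.0738 without the same 3 libraries. Without the library that set the size, GZF3 (adjusted p = 0.00286), NUP192 (adjusted p = 1.37e-06), RSM26 (adjusted p = 5.66e-07) and GCD14 (adjusted p = 0.0167) still passed, with the smaller changes given, and URA3 did not (adjusted p = 0.977). The calls of GZF3, NUP192, RSM26 and GCD14 were lost in limma-voom, with the replicate block and with only the libraries compared, and that of URA3 in the first 2 of these. DESeq2 gave no adjusted p for these 5 genes, so it neither made nor refused a call, and its changes were -6.48, -5.27, -6.83, -7.15 and -4.33. MCM5 for MMS in the wild type lost its call without WT_MMS_2, at 0.13 (adjusted p = 0.302). So did GEX1 for the strains with MMS, at -0.01 (adjusted p = 0.977). MCM5 for the strains with MMS still passed without WT_MMS_2, at -0.58 (adjusted p = 0.000426).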
